A study of Kluyveromyces marxianus and Saccharomyces cerevisiae with 12 samples.

How the data were processed

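Total RNA was extracted with acid phenol and chloroform and 1 μg went into TruSeq V2 RNA-Seq libraries, per the labels' protocols, and the libraries were sequenced on a HiSeq2500. The submitters' processing notes name Trim Galore 0.4.3.1, FastQC 0.10.1, TopHat2 2.0.8, Cufflinks 2.2.1.2 and Cuffdiff 2.2.1.5, without their roles. The genome builds and annotations are not given in the sources used here. The labels call the 3 samples of a group replicates but do not say whether they came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

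The authors deposited 67 tables of FPKM, per the file headers in the layout of Cufflinks gene tracking, with a lower and an upper FPKM bound per gene. A sample had 3 to 13 tables, 32 for *K. marxianus* and 35 for *S. cerevisiae*. The labels do not say how the tables of a sample differ. They were treated as technical parts of 1 sample and averaged to 1 value per gene, so n is 3 per group. A table's short-gene offset is its log2 difference from the sample's other tables, genes up to 400 nt minus genes over 1000 nt. It exceeded 0.3 in 1 table of *K. marxianus* replicate 2 at 6 h (0.58) and 1 of replicate 3 at 36 h (0.78). Both tables enter the main averages. Values that Cufflinks marked LOWDATA or FAIL, 162 in all, were treated as missing. In 61 tables the squared ratio of 2 times the FPKM to its distance from the upper bound gave whole fragment numbers, checked below 5.5 fragments with a tolerance of 0.02. The median share that came out whole was 95.1% in *K. marxianus* and 79.7% in *S. cerevisiae*. In the other 6 tables, 4 of *K. marxianus* replicate 2 at 6 h and 2 of *S. cerevisiae* replicate 3 at 6 h, it did not, and the depth is unknown. These 6 tables are also the ones with LOWDATA values.

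*K. marxianus* symbols came from a RefSeq gene table of assembly Kmar_1.0, strain DMKU3-1042. It matched 5095 of 5319 locus tags and gave a symbol for 4352; 206 loci share their symbol with another locus. Chromosome, start and end were identical for 96.2% of the matched loci, so coordinates are those of the tables, and the strain sequenced differs from the strain of that assembly. *S. cerevisiae* tables name 444 loci and leave 6017 with a locus tag. The annotation at hand was of strain S288C, whose identifiers differ from these tags, so the planned gene lists for *S. cerevisiae* and the planned test of a strain difference were not run.

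Genes with a mean FPKM of at least 1 over the 6 samples of a yeast were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, the later time minus 6 h, and Benjamini-Hochberg adjustment at 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low genes. Of 42 gene lists written before the data were examined, 38 had at least 5 tested members in *K. marxianus* and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 38. The cell wall mannoprotein, flocculation and ammonium assimilation lists had 3, 4 and 4 tested members, and the list of mitochondrially encoded genes matched 0 symbols. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list's genes move on balance one way, and camera whether they move more than other genes, so they ask different questions. With fry 14 lists passed, 11 of them among the 14 that passed camera.

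The rule for the genes named was fixed before the data were examined. It takes the 6 largest rises and the 6 largest falls among called genes with a symbol, a mean of at least 10 FPKM in the higher group and no overlap between times, up to 2 rises and 2 falls of each list described, and 12 symbols named whatever their values. For *S. cerevisiae* loci without a name, 2 rises and 2 falls are given, a part that was not in the rule fixed beforehand. Other loci that carry a named gene's symbol, RNA loci that overlap a named one, EC1118_1E8_RPR1 and members of lists with under 5 tested genes, such as CWP1 and MUC1, were named after their values were seen.

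The tests were run on simulated data with normal noise drawn from the real gene means and spreads, with 200 genes changed. In the simulated *K. marxianus* comparison of 4929 genes, 2.00% of the 50 genes changed 1.5-fold, 26.0% of those changed 2-fold, 84.0% of those changed 4-fold and 96.0% of those changed 8-fold were recovered, with 1 false call. In the simulated *S. cerevisiae* comparison of 5712 genes the shares were 24.0%, 58.0%, 92.0% and 98.0%, with 4 false calls. The changed genes were drawn above a set expression level, and were a smaller share than was called in the real data. The recovered shares therefore do not give the sensitivity of the real comparisons, or that for low genes. In the simulated list test over 38 lists and independent genes, the 1 shifted list was recovered and 0 others were called. Alternatives were other pseudocounts, filters, scalings, ways of combining tables, no trend, a replicate block, each sample left out, and limma's voom on recovered fragments. Figures were drawn with matplotlib in Python.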

Results

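RNA was sequenced from 2 wine yeasts at an early and a later point of an alcoholic fermentation. *Saccharomyces cerevisiae* EC1118 is a commercial wine strain, sampled at 6 h and 20 h. *Kluyveromyces marxianus* IWBT Y855 belongs to a non-*Saccharomyces* species found in must, sampled at 6 h and 36 h. Each of the 4 groups had 3 samples. The cultures grew at 25 °C in a medium with 200 mg/l of assimilable nitrogen, 10 mg/l of phytosterols and sugars at 230 g/l. Expression was given as FPKM, fragments scaled to transcript length and to the total of mapped fragments, for 5319 *K. marxianus* and 6461 *S. cerevisiae* loci. Fragment totals, in units of 1000000 fragments (M), were recovered from the intervals around the FPKM values. These totals are approximate and may be too low, since the whole-number check covered only values below 5.5 fragments. They were 6.70, 5.36 and 6.59 M for *K. marxianus* replicates 1, 2 and 3 at 6 h, and 4.28, 10.5 and 7.01 M at 36 h. For *S. cerevisiae* they were 21.6, 9.34 and 1.51 M at 6 h, and 7.67, 6.39 and 5.498 M at 20 h. The totals of 5.36 and 1.51 M cover part of the tables of those samples (3 of 7 and 1 of 3), because the other tables did not give a depth.

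In both yeasts the 6 samples separated by time. The first principal component of log2(FPKM + 1) held 69.7% of the variance in *K. marxianus* and 69.5% in *S. cerevisiae*. *K. marxianus* replicate 1 at 6 h stood apart from the other samples of its group: Spearman's rho across genes was 0.931 with replicate 2 and 0.924 with replicate 3, against 0.984 between replicates 2 and 3. At 36 h it was 0.953 between replicates 1 and 2, 0.938 between 1 and 3 and 0.956 between 2 and 3, so the 6 h values of replicate 1 lie just below the 36 h values. In *S. cerevisiae* at 6 h, rho was 0.953 and 0.948 between replicate 1 and the others, and 0.980 between replicates 2 and 3. At 20 h it was 0.979 between replicates 1 and 2, and 0.948 and 0.941 between replicate 3 and these. The ribosomal RNA locus EFG00000987821 was at 3062 FPKM in *S. cerevisiae* replicate 1 at 6 h and listed at 0 in the other 5 samples. Another such locus, EFG00000987812, was above 0 in all samples.

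**Figure D1:**
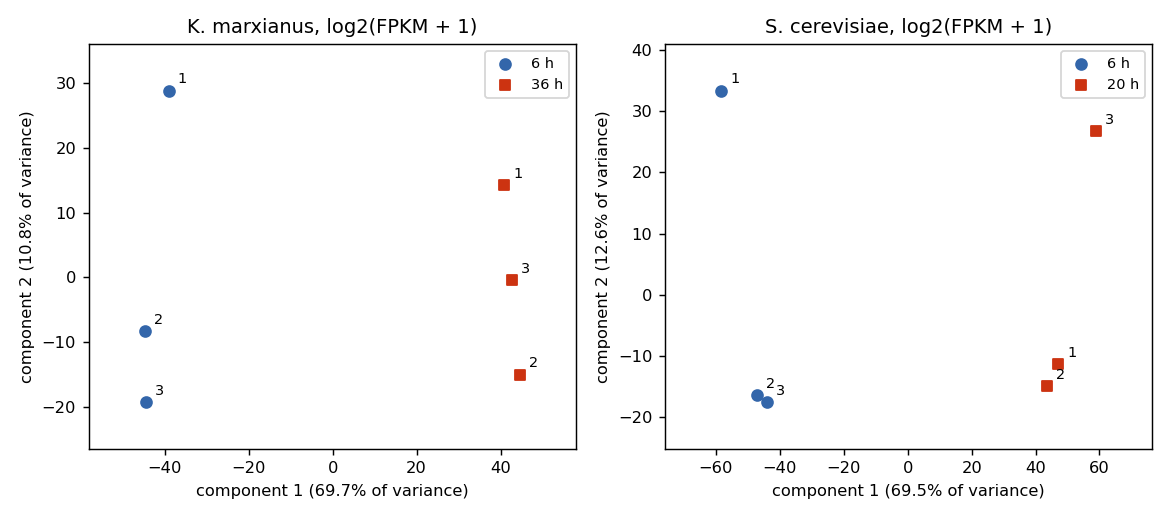
Samples on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis; points are single samples, numbered by replicate, circles for 6 h and squares for the later time. The first component holds 69.7% of the variance in K. marxianus and 69.5% in S. cerevisiae and separates the times, and on the second component replicate 1 at 6 h lies apart from replicates 2 and 3 in both, as does replicate 3 at 20 h from replicates 1 and 2 in S. cerevisiae.

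The first question was which *K. marxianus* genes differed between 6 h and 36 h of fermentation. Of 4929 genes tested with limma, 2008 passed a Benjamini-Hochberg adjusted p of 0.05: 1048 were higher and 960 lower at 36 h. A change of at least 2-fold was found for 1629 of these, 876 higher and 753 lower. Without replicate 2 at 6 h, the number of lower genes was 594. Of 38 gene lists tested with camera, 14 passed with a preset correlation and 0 with an estimated one. Other splits of the 6 samples, each of which mixed the times, gave up to 22 lists with the preset correlation.

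The 6 largest rises and 6 largest falls were taken among called genes with a symbol in which the samples of the times did not overlap. Positions are those given in the tables. HSP26 (KLMA_40128, chromosome 4, 280291 to 280872), a small heat shock protein, went from 45.5 ± 38.6 FPKM at 6 h to 4614 ± 968 FPKM at 36 h (SD, n = 3), a log2 change of 7.38 ± 0.85 (SE) with a limma adjusted p of 0.000164. At 6 h it was 3.63 FPKM in replicate 1, and 79.7 and 53.0 FPKM in replicates 2 and 3. The locus with the symbol yciC (KLMA_20012, chromosome 2, 35950 to 37560) rose from 4.48 ± 3.70 to 738 ± 183 FPKM. ADH4 (KLMA_20005, chromosome 2, 19014 to 20270), which encodes an alcohol dehydrogenase, rose from 10.9 ± 3.28 to 833 ± 81.0 FPKM. URC1 (KLMA_50535, chromosome 5, 1153308 to 1154609), a gene of uracil breakdown, rose from 12.4 ± 5.95 to 694 ± 163 FPKM. SPG4 (KLMA_30101, chromosome 3, 240279 to 240584) rose from 31.9 ± 28.3 to 828 ± 226 FPKM, and INO1 (KLMA_50488, chromosome 5, 1048724 to 1050316), the inositol phosphate synthase gene, from 21.0 ± 6.40 to 559 ± 26.4 FPKM.

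HTB2 (KLMA_60118, chromosome 6, 266180 to 266578), a histone H2B gene, fell from 1601 ± 798 to 15.2 ± 4.97 FPKM. LYS9 (KLMA_40016, chromosome 4, 37386 to 38723), of lysine synthesis, fell from 1703 ± 501 to 27.2 ± 20.8 FPKM, a log2 change of -6.12 ± 0.45 with a limma adjusted p of 1.58e-05. TUB2 (KLMA_70056, chromosome 7, 105577 to 106926), the beta-tubulin gene, fell from 293 ± 91.0 to 5.74 ± 5.04 FPKM. DSE2 (KLMA_20758, chromosome 2, 1541517 to 1542167), a gene of daughter cell separation, fell from 173 ± 28.0 to 3.39 ± 1.54 FPKM, and HHF2 (KLMA_80118, chromosome 8, 270973 to 271284), a histone H4 gene, from 1780 ± 307 to 47.6 ± 15.8 FPKM. BET5 (KLMA_40448, chromosome 4, 1019001 to 1019557) was at 68.0, 76.1 and 54.7 FPKM in the 6 h samples and was listed at 0 in the 36 h samples. BET5 encodes a subunit of a vesicle transport complex. No *K. marxianus* value at 36 h was marked LOWDATA or FAIL, so the 0 is not a marked failure. Whether the RNA was absent was not tested.

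Of 6 lists of amino acid synthesis genes, 5 passed as lower at 36 h. Sulfur assimilation and methionine did not, with 6 of 23 higher, 5 lower and a median of 0.16. All 15 tested genes for lysine and histidine were lower (15 adjusted over the list alone), with a median log2 change of -3.22. LYS4 fell from 250 ± 69.9 to 14.2 ± 2.73 FPKM. Of 11 branched-chain genes 10 were lower and 0 higher (10 adjusted over the list alone). The LEU4 locus KLMA_50402, of leucine synthesis, fell from 4959 ± 3223 to 138 ± 55.5 FPKM, ILV5 from 2437 ± 290 to 328 ± 79.9 FPKM, and BAT1, a branched-chain aminotransferase gene, from 1417 ± 673 to 323 ± 210 FPKM. In the arginine, proline and glutamate-family list 9 of 12 were lower (10 adjusted over the list alone). ARG7 fell from 194 ± 96.8 to 5.37 ± 2.27 FPKM and ARG4 from 553 ± 266 to 33.9 ± 10.4 FPKM, while CPA1 was at 453 ± 146 and 461 ± 120 FPKM (limma adjusted p = 0.921). For aromatic amino acids 10 of 14 were lower and 2 higher (12 adjusted over the list alone). TRP3 fell from 170 ± 75.3 to 13.4 ± 0.599 FPKM and TRP5 from 509 ± 257 to 52.9 ± 10.5 FPKM, while TRP1 and ARO8 rose, TRP1 by a log2 change of 1.69 and the ARO8 locus KLMA_50151 from 58.3 ± 15.9 to 185 ± 26.7 FPKM. The other ARO8 locus, KLMA_20259, did not pass (limma adjusted p = 0.475). For serine, glycine and threonine 8 of 15 were lower (8 adjusted over the list alone), among them SER1, from 346 ± 139 to 44.2 ± 19.8 FPKM. The camera adjusted p with a preset correlation was 1.85e-09 for lysine and histidine, 2.465e-06 for branched-chain, 0.000116 for arginine, 0.00117 for aromatic and 0.00100 for serine genes. It was adjusted p = 0.813 for each of the 5 lists with an estimated correlation. At 6 h replicate 1 lay below the mean of replicates 2 and 3 in these lists, by medians of -1.37 (arginine), -1.14 (aromatic), -1.10 (lysine and histidine), -0.59 (serine) and -0.49 (branched-chain) on the log2 scale.

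**Figure D2:**
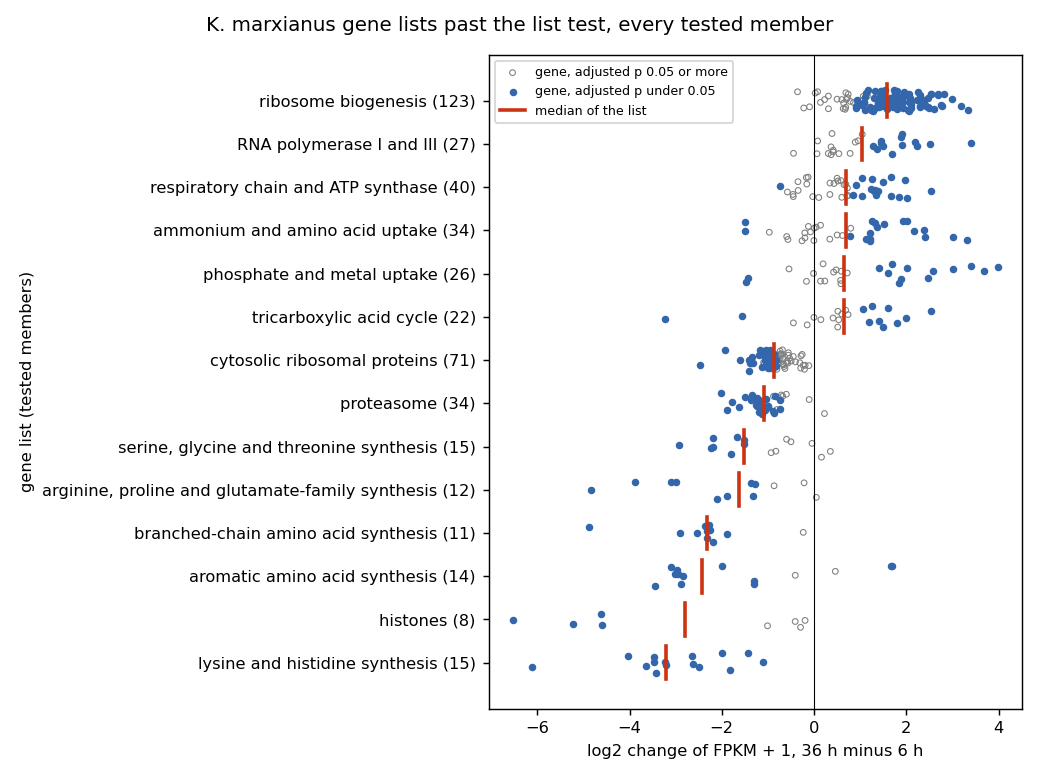
Log2 change of FPKM + 1 from 6 h to 36 h (horizontal axis) for every tested member of the 14 K. marxianus gene lists past the list test with a preset correlation (0 passed with an estimated one); filled points are genes with an adjusted p under 0.05, open points the others, and red bars the list medians. The medians run from -3.22 for lysine and histidine synthesis to 1.57 for ribosome biogenesis.

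In the list of ammonium and amino acid uptake 16 of 34 were higher and 2 lower (18 adjusted over the list alone), with a camera adjusted p of 0.00827, or adjusted p = 0.925 with an estimated correlation. This list did not pass with fry (adjusted p = 0.0601). MEP3, an ammonium permease gene, rose from 15.3 ± 5.74 to 155 ± 26.5 FPKM and the DUR3 locus KLMA_20006, a urea transporter gene, from 11.2 ± 2.94 to 95.6 ± 11.5 FPKM. Of the other DUR3 loci, KLMA_30305 rose from 17.6 ± 4.02 to 75.6 ± 25.4 FPKM and KLMA_40009 did not pass (log2 change -0.97, limma adjusted p = 0.168). TAT2 fell from 133 ± 40.9 to 45.7 ± 8.38 FPKM and the MUP1 locus KLMA_20366 from 27.4 ± 13.9 to 8.40 ± 1.68 FPKM, while the other MUP1 locus, KLMA_30073, did not pass (limma adjusted p = 0.605). MEP2, another ammonium permease gene, was at 20.7 ± 7.999 and 21.8 ± 10.7 FPKM (limma adjusted p = 0.996). The symbol GAP1 is carried by 2 loci, and in *Kluyveromyces* it names both an amino acid permease and a glyceraldehyde-3-phosphate dehydrogenase. KLMA_10394 rose from 4.00 ± 0.710 to 25.6 ± 4.94 FPKM. KLMA_40218 was at 7367 ± 2229 and 11126 ± 2585 FPKM (limma adjusted p = 0.161). Among targets of nitrogen catabolite repression, by which preferred nitrogen sources shut off the use of others, 17 of 44 were higher and 7 lower (25 adjusted over the list alone). The camera adjusted p was 0.191. The median log2 change was 0.39, and ran from 0.094 to 0.63 with samples left out, and replicate 1 at 6 h lay by a median of -0.59 from the other 6 h samples. CAR1 fell from 442 ± 41.1 to 72.3 ± 30.4 FPKM and DCG1 from 66.6 ± 29.5 to 6.16 ± 4.66 FPKM. Of 17 nitrogen regulators 3 were higher and 0 lower (1 adjusted over the list alone), with a camera adjusted p of 0.955; GLN3 was at 104 ± 58.5 and 41.4 ± 7.29 FPKM (limma adjusted p = 0.0799). Without replicate 1 at 6 h its adjusted p was 0.00105, and over all alternatives it ran from 0.00105 to 0.243.

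In ammonium assimilation, a list with 4 tested members, too few for the list test, GLN1 (glutamine synthetase) was at 625 ± 140 and 1228 ± 314 FPKM (limma adjusted p = 0.0301) and GDH2, a glutamate dehydrogenase gene, at 137 ± 65.2 and 48.9 ± 15.2 FPKM (limma adjusted p = 0.0160). Both calls were lost when single samples were left out. For GLN1 the adjusted p was 0.0799 and 0.0735 without replicates 1 and 2 at 6 h, and 0.0670 and 0.0790 without replicates 1 and 2 at 36 h. For GDH2 it was 0.0651 without replicate 2 at 6 h, and 0.0593 and 0.0514 without replicates 1 and 2 at 36 h. Over all alternatives it ran from 0.0199 to 0.0799 for GLN1 and from 0.00226 to 0.0651 for GDH2. GDH3 and GLT1 of the same list did not pass. In the Ehrlich pathway, which turns amino acids into higher alcohols, 6 of 17 were higher and 4 lower (11 adjusted over the list alone; camera adjusted p = 0.646). The list passed with fry (adjusted p = 0.0403; range over all alternatives 0.0403 to 0.963). ARO10, a decarboxylase gene of this pathway, fell from 377 ± 163 to 39.7 ± 3.43 FPKM, while ARO9 was at 25.9 ± 3.57 and 24.9 ± 4.26 FPKM (limma adjusted p = 0.864). The symbol ADH3 is carried by 2 loci that moved apart: KLMA_80306 rose by a log2 change of 3.93, to 522 ± 115 FPKM, and KLMA_20158 fell from 210 ± 96.9 to 38.1 ± 23.3 FPKM. Of 5 genes for acetate and ethyl esters 2 were higher and 1 lower (4 adjusted over the list alone; camera adjusted p = 0.823). The symbols GDH1, BAT2 and ATF1 were not carried by a tested locus.

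**Figure D3:**
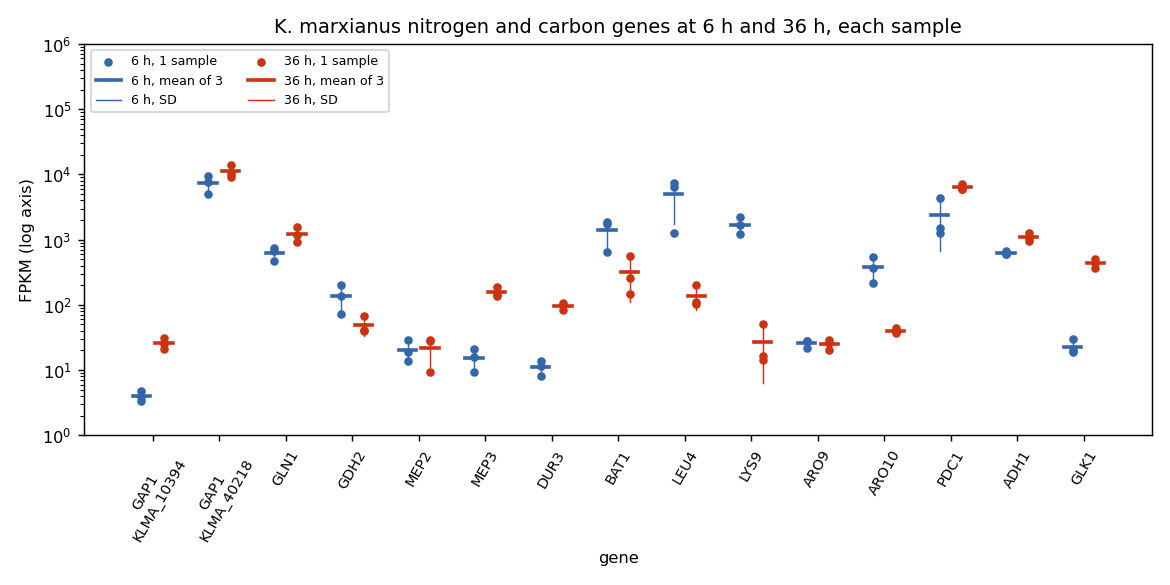
FPKM (log axis) of 15 K. marxianus loci for nitrogen and carbon use, with 3 samples at 6 h (blue) and 3 at 36 h (red); thick lines are means, thin lines the SD. MEP3 rises from 15.3 to 155 FPKM and LYS9 falls from 1703 to 27.2 FPKM, while MEP2 stays at 20.7 and 21.8 FPKM.

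Among called genes, those of ribosome biogenesis were higher at 36 h and those of cytosolic ribosomal proteins lower. Of 123 ribosome biogenesis genes 98 were higher and 0 lower (102 adjusted over the list alone), with a median log2 change of 1.57. DBP2 rose from 53.2 ± 40.3 to 464 ± 101 FPKM and DBP7 from 4.96 ± 4.58 to 43.7 ± 3.78 FPKM; both encode RNA helicases. Of 27 genes for RNA polymerases I and III 13 were higher and 0 lower (14 adjusted over the list alone); RRN5 rose from 4.39 ± 1.05 to 55.7 ± 2.66 FPKM. Of 71 cytosolic ribosomal protein genes 33 were lower and 0 higher (36 adjusted over the list alone), with a median of -0.86. RPS31 fell from 4075 ± 436 to 742 ± 163 FPKM and RPL9A from 1566 ± 291 to 412 ± 102 FPKM. The camera adjusted p was 3.01e-17, 9.82e-05 and 2.49e-08 for the 3 lists in this order, and adjusted p = 0.813 for each with an estimated correlation. With fry, ribosome biogenesis (adjusted p = 0.0571) and cytosolic ribosomal proteins (0.0551) did not pass, while RNA polymerases I and III did (0.0403). Replicate 1 at 6 h lay above the other 6 h samples in ribosome biogenesis, by a median of 1.31, and without it the median log2 change of that list was 2.05. In the RNA polymerase list it lay above them by a median of 0.83. Of 70 mitochondrial ribosome genes 7 were higher and 6 lower (1 adjusted over the list alone; camera adjusted p = 0.955).

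In the proteasome list 26 of 34 were lower and 0 higher (30 adjusted over the list alone); RPN9 fell from 162 ± 16.0 to 39.5 ± 9.12 FPKM. Of 8 histone genes 4 were lower and 0 higher (5 adjusted over the list alone). The camera adjusted p was 4.73e-08 for the proteasome and 0.000329 for histones, and adjusted p = 0.813 for both with an estimated correlation. In DNA replication and cell cycle 12 of 39 were lower and 3 higher (15 adjusted over the list alone; camera adjusted p = 0.0722). This list passed without replicate 2 (adjusted p = 0.0182) or 3 (0.0125) at 6 h and without replicate 1 at 36 h (0.0460), and over all alternatives its adjusted p ran from 0.0125 to 0.963. Its median log2 change was -0.35, and ran from -0.69 to -0.17 with samples left out. Replicate 1 at 6 h lay above the other 6 h samples in this list by a median of 0.85. CLB2, a mitotic cyclin gene, fell from 31.1 ± 16.8 to 2.70 ± 1.57 FPKM, while CLN3, a G1 cyclin gene, rose from 152 ± 27.3 to 625 ± 44.3 FPKM.

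Respiration and metal uptake genes were higher in part. Of 40 genes for the respiratory chain and ATP synthase 17 were higher and 1 lower (18 adjusted over the list alone); COX16 rose from 179 ± 48.9 to 1008 ± 59.0 FPKM. In the tricarboxylic acid cycle 9 of 22 were higher and 2 lower (12 adjusted over the list alone). MDH2 rose from 177 ± 27.9 to 1038 ± 233 FPKM. Of 26 genes for phosphate and metal uptake 12 were higher and 2 lower (15 adjusted over the list alone). FET4, an iron transporter gene, rose from 48.8 ± 9.02 to 635 ± 100.3 FPKM, and KLMA_40087, a locus with the symbol ARN2, from 13.5 ± 6.15 to 225 ± 92.4 FPKM. The camera adjusted p was 0.00121, 0.0169 and 0.000343 for these 3 lists, and adjusted p = 0.813 for each with an estimated correlation. The tricarboxylic acid list was lost without replicate 1 at 6 h (adjusted p = 0.0645), and over all alternatives its adjusted p ran from 0.00779 to 0.813. The 9 tested loci on the mitochondrial sequence, a group chosen after its values were seen, had a median log2 change of -0.76; 0 passed with limma, 1 had an unadjusted p under 0.05, and 0 passed with voom on recovered fragments.

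Sugar use genes did not pass as lists in the main test. Of 12 genes for glycolysis and ethanol formation 4 were higher and 0 lower (3 adjusted over the list alone; camera adjusted p = 0.0722). GLK1, a glucokinase gene, rose from 22.8 ± 6.06 to 435 ± 68.9 FPKM and PDC1, the pyruvate decarboxylase gene, from 2358 ± 1684 to 6432 ± 652 FPKM; at 6 h PDC1 was at 4296 FPKM in replicate 1, and at 1532 and 1247 FPKM in the others. This list passed without replicate 1 at 6 h (adjusted p = 0.0196) or replicate 3 at 36 h (0.0411), and over all alternatives its adjusted p ran from 0.0196 to 0.925. Replicate 1 at 6 h lay above the other 6 h samples in it by a median of 0.59. ADH1 was at 627 ± 40.3 and 1104 ± 156 FPKM (limma adjusted p = 0.0323), and its adjusted p was 0.0562, 0.0902 and 0.0970 without replicates 1, 2 and 3 at 6 h, and 0.0859 without replicate 2 at 36 h (range over all alternatives 0.0147 to 0.0970). Of 17 sugar uptake genes 7 were higher and 1 lower (8 adjusted over the list alone; camera adjusted p = 0.0585). That list passed without replicate 3 at 6 h (adjusted p = 0.0435), and without replicate 1 (0.0460) or 2 (0.0411) at 36 h, and over all alternatives its adjusted p ran from 0.0297 to 0.813. It also passed with fry (adjusted p = 0.0403), and with camera on the median over the tables (0.0297) or without tables with a short-gene offset (0.0455). Among 4 loci with the symbol LAC12, a lactose permease gene, KLMA_30010 rose from 21.6 ± 2.18 to 99.8 ± 21.2 FPKM and the others did not pass, though KLMA_20830 passed as lower without replicate 1 at 6 h (adjusted p = 0.0129). The symbol STL1, a glycerol transporter gene, is carried by 2 loci: KLMA_60180 fell from 118 ± 12.8 to 17.7 ± 6.66 FPKM and KLMA_30607 rose from 33.0 ± 4.28 to 78.1 ± 10.5 FPKM.

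Among lipid and nucleotide lists, ergosterol synthesis had 12 of 24 lower and 3 higher (16 adjusted over the list alone; camera adjusted p = 0.0745), and passed without replicate 2 (adjusted p = 0.0270) or 3 (0.0320) at 6 h (range over all alternatives 0.0270 to 0.963). In this list replicate 1 at 6 h lay above the other 6 h samples by a median of 0.60. ERG8 fell from 75.2 ± 7.90 to 8.02 ± 1.44 FPKM and HMG1 rose from 148 ± 25.2 to 611 ± 99.4 FPKM. Purine and pyrimidine synthesis had 10 of 22 lower and 4 higher (16 adjusted over the list alone; camera adjusted p = 0.0745), and passed without replicate 2 (adjusted p = 0.0333) or 3 (0.0454) at 6 h (range over all alternatives 0.0333 to 0.963), and replicate 1 at 6 h lay above the others by a median of 0.55. Fatty acid synthesis had 1 of 13 higher and 2 lower (3 adjusted over the list alone), and fatty acid oxidation and peroxisome 3 of 24 higher and 3 lower (4 adjusted over the list alone), with camera adjusted p of 0.646 and 0.823.

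In the stress lists, heat shock proteins and chaperones had 2 of 19 higher and 6 lower (8 adjusted over the list alone; camera adjusted p = 0.292). HSP26 rose, while SSA2, an HSP70 chaperone gene, fell from 515 ± 153 to 64.9 ± 14.8 FPKM. Oxidative stress defence had 6 of 23 higher and 4 lower (11 adjusted over the list alone; camera adjusted p = 0.955), with CTA1 and CTT1, both catalase genes, moving apart: CTA1 rose from 22.1 ± 4.35 to 105.2 ± 31.3 FPKM and CTT1 fell from 1182 ± 534 to 316 ± 59.1 FPKM. Trehalose and glycogen had 2 of 12 higher and 1 lower (1 adjusted over the list alone; camera adjusted p = 0.926). Multidrug transport and weak acid response had 6 of 17 higher and 1 lower (7 adjusted over the list alone; camera adjusted p = 0.119), with the PDR12 locus KLMA_30363 up from 236 ± 132 to 1144 ± 177 FPKM. The other PDR12 locus, KLMA_30362, did not pass (limma adjusted p = 0.954). Autophagy and vacuolar proteases had 10 of 46 higher and 7 lower (17 adjusted over the list alone; camera adjusted p = 0.590).

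The other lists did not pass camera either. Sulfur assimilation and methionine had 6 of 23 higher and 5 lower (12 adjusted over the list alone; camera adjusted p = 0.641). Glycerol, acetate and redox had 6 of 17 higher and 5 lower (11 adjusted over the list alone; camera adjusted p = 0.987), with a median of 0.37, a mean of -0.07 and an upward list test. The pentose phosphate pathway had 2 of 8 lower (2 adjusted over the list alone; camera adjusted p = 0.601), and vitamin and thiamine synthesis 3 of 23 higher and 3 lower (2 adjusted over the list alone; camera adjusted p = 0.987). Sporulation and meiosis had 7 of 18 higher and 2 lower (9 adjusted over the list alone; camera adjusted p = 0.134), and passed with fry (adjusted p = 0.0403; range over all alternatives 0.0403 to 0.925). Mating and haploid-specific genes had 6 of 18 higher and 4 lower (10 adjusted over the list alone; camera adjusted p = 0.976), with STE3, a pheromone receptor gene, down from 52.8 ± 23.9 to 1.26 ± 0.656 FPKM. Lactose, inulin and pectin use had 3 of 10 higher and 1 lower (3 adjusted over the list alone; camera adjusted p = 0.479); PGU1, a polygalacturonase gene, rose from 19.7 ± 6.96 to 269 ± 133 FPKM. Nitrogen regulators had a median of -0.11, a mean of 0.07 and an upward list test, and mating genes a median of -0.12, a mean of 0.00084 and a downward one.

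The second question was which *S. cerevisiae* loci differed between 6 h and 20 h. Of 5712 loci tested with limma, 3444 passed: 2268 were higher and 1176 lower at 20 h, and 1978 changed at least 2-fold, 1319 higher and 659 lower. The median log2 change over all loci was 0.30, so these changes are relative to the total of mapped fragments. With median-ratio scaling between samples the median was -0.01 and the split was 1716 higher and 1737 lower, and with quantile normalization it was 1704 higher and 1574 lower. For changes of at least 2-fold the split was 878 higher and 946 lower with median-ratio scaling, and 944 higher and 822 lower with quantile normalization. The tables name 444 of the loci, which are RNA genes, and the other 6017 carry only a locus tag that was not paired with a gene name here.

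The locus EC1118_1M3_3642g rose from 158 ± 51.5 to 77100 ± 15664 FPKM (SD, n = 3), a log2 change of 8.96 ± 0.29 with a limma adjusted p of 7.47e-06, and was the most abundant locus in each of the 3 samples at 20 h, with 5.86%, 7.76% and 7.50% of all FPKM. EC1118_1M3_2795g rose from 1.89 ± 1.22 to 628 ± 287 FPKM. EC1118_1J11_2696g fell from 2201 ± 927 to 11.2 ± 2.16 FPKM. EC1118_1L7_1420g was at 1077, 1174 and 2125 FPKM in the 6 h samples, at 634 FPKM in replicate 1 at 20 h, and listed at 0 in the other 2. Its limma adjusted p was 0.0311, and 0.0649, 0.0696 and 0.0820 without replicates 1, 2 and 3 at 6 h, and 0.0932 and 0.0941 without replicates 2 and 3 at 20 h (range over all alternatives 8.76e-05 to 0.0941). With the median over the tables it was 0.0689.

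Of 74 named RNA loci tested 3 were higher, 6 lower and 65 did not pass. How well these libraries captured such RNAs was not tested, so the changes are those of the listed FPKM. The locus EFG00000987867, named for the small nucleolar RNA snR11, rose from 8.49 ± 3.25 to 57.9 ± 6.18 FPKM (log2 change 2.68 ± 0.25). The overlapping locus EC1118_1M3_snR11 was at 66.8 ± 26.6 and 73.9 ± 23.2 FPKM (limma adjusted p = 0.698), so these tables do not show that the RNA itself rose. EC1118_1O4_snR17a rose from 5.89 ± 1.17 to 11.7 ± 0.565 FPKM and EC1118_1M3_snR86 from 25.4 ± 1.81 to 48.7 ± 10.8 FPKM, and neither passed with quantile normalization (adjusted p = 0.0709 and 0.0619). Over all alternatives the adjusted p ran from 0.00151 to 0.0709 and from 0.00317 to 0.0619. The first of these overlaps the locus Fungi_U3 (EFG00000987914), which was at 29.7 ± 30.9 and 17.9 ± 22.4 FPKM (limma adjusted p = 0.427). The snR49 locus EFG00000987888 was at 17.9, 12.4 and 18.7 FPKM in the 6 h samples and listed at 0 in the 20 h samples, and it overlaps EC1118_1N18_snR49, a lower locus described with the other falls. It rests on 4.27 recovered fragments at 6 h. It did not pass without the smallest table of each sample (adjusted p = 0.0809), with voom (0.205) or with the median over the tables, and over all alternatives its adjusted p ran from 4.14e-05 to 1.

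Among the other 5 lower RNA loci, EC1118_1N18_snR49 was at 63.8, 21.3 and 15.2 FPKM at 6 h, at 12.6 FPKM in replicate 1 at 20 h, and listed at 0 in the other 2 (limma adjusted p = 0.0232). Its adjusted p was 0.07305 without replicate 1 at 6 h, and 0.0714 and 0.0718 without replicates 2 and 3 at 20 h (range over all alternatives 0.00170 to 0.362). This locus rests on 10.9 recovered fragments at 6 h and 0.49 at 20 h. EC1118_1G1_snR7-L was at 18.5, 24.8 and 33.7 FPKM at 6 h, at 7.90 FPKM in replicate 2 at 20 h, and listed at 0 in the others. Its recovered fragments were 28.8 at 6 h and 1.24 at 20 h. The overlapping EC1118_1G1_snR7-S did not pass (limma adjusted p = 0.340). EC1118_1M3_snR83 went from 48.5 ± 2.99 to 26.5 ± 12.2 FPKM (limma adjusted p = 0.0324), with adjusted p of 0.0737, 0.0861 and 0.0655 without replicates 1, 2 and 3 at 6 h and 0.0775 without replicate 1 at 20 h (range over all alternatives 0.00484 to 0.122). EC1118_1B15_TLC1 went from 23.4 ± 2.70 to 16.0 ± 3.04 FPKM (limma adjusted p = 0.0350). Without replicates 2 and 3 at 6 h its adjusted p was 0.0826 and 0.114, and without replicates 1 and 3 at 20 h it was 0.0629 and 0.0565 (range over all alternatives 0.00247 to 0.114). The overlapping locus Sacc_telomerase (EFG00000987602) did not pass (log2 change -0.55, limma adjusted p = 0.422). The last, EC1118_1E8_RPR1, was below 10 FPKM in every sample and is outside the rule for named loci. The locus RNaseP_nuc (EFG00000987671), which overlaps it, did not pass (log2 change 0.23, limma adjusted p = 0.842).

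The tables did not allow a test of whether the change with time differed between the yeasts, and the later time was 36 h in one and 20 h in the other. The counts of changed genes are therefore not compared between them.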

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

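Tests chosen after the data were seen are voom on recovered fragments, the means without tables with a short-gene offset, and for gene lists the median over the tables and the lists without locus KLMA_40218. Of the 162 alternative values for counts of genes and lists, 160 stayed within 1.5 times the main count. With an estimated correlation 0 of the 38 lists passed (14 with the preset correlation). The lowest adjusted p was then 0.813, and 0 lists had an unadjusted p under 0.05. Fry passed 14. The camera runs differed in how the correlation was set, and other effects of that setting on the test were not separated from the correlation. Leaving out single samples gave 1426 to 1914 called genes in *K. marxianus*, 791 to 1021 higher, 594 to 1023 lower and 1404 to 1609 changed at least 2-fold, with 594 lower without replicate 2 at 6 h; the cause was not tested. In *S. cerevisiae* the ranges were 2935 to 3433, 1977 to 2170, 958 to 1263 and 1865 to 2036. The number of lists ran from 14 to 18. Under the other alternatives the called genes ran from 1866 to 2251 in *K. marxianus* and from 3239 to 3582 in *S. cerevisiae*. A replicate block gave 1866 and 3239 called genes and 14 lists. These 14 included DNA replication and cell cycle, and did not include the tricarboxylic acid cycle. The replicate numbers do not pair the samples: same-numbered deviations correlated at 0.043, -0.074 and -0.23 in *K. marxianus* and -0.12, 0.17 and 0.032 in *S. cerevisiae*, and not every sample correlated best with its own number.

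Directions that changed belong to values that did not pass the main test, except for snR49, and the cause was not tested. MEP2 (main log2 change -0.0035) was at 0.013 with a pseudocount of 5, 0.0025 with median-ratio scaling, 0.0080 with quantile normalization, 0.049 with the median over the tables, 0.016 without tables with a short-gene offset, and -0.26 to 0.49 with samples left out. CPA1 was at -0.087 with quantile normalization and -0.24 to 0.25 with samples left out. With samples left out GLY1 (0.16 with all samples) ran from -0.27 to 0.61, TPI1 (-0.18) from -0.40 to 0.0015, RPN4 (0.23) from -0.073 to 0.65 and ARO9 from -0.18 to 0.076. The snR49 locus EFG00000987888 was at 0 with the median over the tables. List medians with a turned list test were -0.10 for nitrogen regulators and -0.083 for mating genes (median over the tables), and 0.37 for glycerol, acetate and redox (replicate block). With samples left out the medians ran from -0.19 to 0.072 for nitrogen regulators, 0.094 to 0.57 for glycerol, acetate and redox, -0.086 to 0.093 for the mitochondrial ribosome, -0.062 to 0.087 for oxidative stress defence, 0.25 to 0.43 for fatty acid oxidation, 0.021 to 0.44 for autophagy, -0.13 to 0.27 for vitamins and -0.21 to -0.046 for mating genes. Medians also changed sign, with the list test's direction kept, for sulfur assimilation (-0.17 to 0.30), the Ehrlich pathway (-0.16 to 0.17), pentose phosphate (-0.21 to 0.023), trehalose (-0.46 to 0.034) and lactose use (-0.17 to 0.43). Of 2819 alternative values for named *K. marxianus* genes, 88 lost the call, 17 gained it and 16 changed direction. The gene lists for *S. cerevisiae* and the strain difference, with their alternatives, were not run. Depth limits the low genes: the samples with recovered totals of 1.51 M and 5.36 M fragments are known only in part.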

Other observations

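The tests chosen after their results were seen are the depth of *K. marxianus* replicate 1, the leave-one-out range of the ribosome lists, the splits of the samples, the shares of the most abundant loci, the exchange of replicates 2 and 3, and the chromosome-end tests other than the first ones within 20 kb, although the rise within 30 kb had been planned before any of these was run.

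In *S. cerevisiae* the most abundant locus of a sample held 2.12% ± 0.195 (SD, n = 3) of all FPKM at 6 h and 7.04% ± 1.03 at 20 h, where it was EC1118_1M3_3642g, of 240 nt. The *S. cerevisiae* shares that follow include this locus, so they are not separate from its own share. Shares without it were not computed. The 10 most abundant loci held 14.9% ± 0.81 of all FPKM at 6 h and 21.1% ± 0.52 at 20 h, and loci under 400 nt held 20.5% ± 0.15 and 26.6% ± 1.98 (exact permutation p = 0.1 for each of the 3 shares, two-sided, the smallest that 3 against 3 samples allow). In *K. marxianus* the 10 most abundant loci held 13.7% ± 1.42 and 16.5% ± 1.52 (exact permutation p = 0.2). Of the *K. marxianus* lists too small for the list test, the cell wall gene CWP1 fell from 1838 ± 578 to 468 ± 48.3 FPKM. The symbol MUC1 is carried by 2 loci that moved apart: KLMA_20428 rose from 25.0 ± 9.93 to 77.8 ± 13.5 FPKM and KLMA_50409 fell by 3.07 on the log2 scale. CCW12, CCW14, FLO5 and FLO8 of the same lists did not pass. These genes were named after their values were seen.

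For the *K. marxianus* gene counts, 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 2008 called genes and the highest other split 1; for changes of at least 2-fold these were 1629 and 1. In each case 1 of the 10 splits, the real one, gave as many. In *S. cerevisiae* the real split gave 3444 and the highest other 1, and for changes of at least 2-fold 1978 and 1, again with 1 of 10 as large. For gene lists the real split gave 14 and the highest other 22, and 7 of the 10 splits gave at least as many. Each of the other splits put samples of both times in each group, so it kept a part of the time change. These splits are therefore not a test on data without such a change. In the real split the correlation estimated within lists ran from 0.046 (acetate and ethyl esters) to 0.81 (arginine), above the preset 0.01 in every list. The preset test therefore treats list genes as less dependent than estimated. Why lists passed in splits that called almost no genes was not tested.

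The opposite movement of ribosome biogenesis and ribosomal protein genes in *K. marxianus* had a difference of medians of 2.44 (bootstrap interval over genes 2.25 to 2.70). The bootstrap intervals given here resample genes, so they do not measure the spread between samples. The correlation that camera estimated between genes was 0.78 in the ribosome biogenesis list and 0.58 in the ribosomal protein list. Taking out a smooth trend of the change on gene length left 2.55 (2.40 to 2.80), and a trend on expression level left 2.70 (2.56 to 2.96), which argues against either as the whole cause. With 1 sample left out the difference ran from 2.25 to 2.87, so no single sample makes it. The time of fermentation may underlie it, as a hypothesis, but sampling time is confounded with anything else that differed between the 6 h and 36 h collections, which was not tested.

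*K. marxianus* replicate 1 at 6 h lay apart from replicates 2 and 3. It had 6.70 M recovered fragments, and replicate 3 had 6.59 M, which argues against low depth. Spearman's rho across genes between gene length and its difference from the other 2 was 0.157, between the bounds set for and against a length bias. A different stage of fermentation could be a candidate explanation: Pearson's r across genes between replicate 1 minus replicate 2 and the 36 h mean minus replicate 3 was 0.239, and 0.199 with replicates 2 and 3 exchanged. This also lies between the bounds, so length bias and stage both stay open; genes are not independent replicates.

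Several of the largest *K. marxianus* rises lie near a chromosome start, which prompted the hypothesis that genes near chromosome ends changed more. Within 20 kb of the outermost locus, 93 tested loci had a mean absolute log2 change of 0.81 against 0.91 for random loci of similar level (one-sided permutation p = 0.9), and the 36 of these with a symbol of their own gave p = 0.48, so sharing of reads between copies could not be judged. Within 30 kb, p was 0.26 for the absolute change. For a rise, p was 0.07 within 20 kb and 0.0095 within 30 kb (145 loci, mean 0.27 against 0.04), and 0.04 without the loci that prompted the test (143 loci). With Benjamini-Hochberg adjustment over these 6 tests the lowest value was 0.057, for the rise within 30 kb. A rise within 30 kb had been planned first, but the absolute change within 20 kb was run before it. The test was prompted by genes in the same data, so a rise near chromosome ends stays an open hypothesis that does not pass the adjustment over the 6 tests.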
